A study of Mus musculus with 304 samples.

How the data were processed

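Patch-seq libraries of single mouse dentate granule cells were prepared, per the labels, from cytosol drawn into a patch pipette and with the Nextera XT kit. The submitters' processing notes name Trimmomatic for trimming, STAR for alignment, featureCounts for counting and the build GRCm38, without versions. The rule behind the quality control labels, the counting strand and other settings are not given in the sources used here. The authors deposited counts, whole-number reads per gene and cell for 22800 genes in 291 cells. The authors also deposited a scaled signal for 252 cells, in which each cell's counts are multiplied by 1 factor (0.187 to 287). The names of the deposited tables point the other way, so the unit of each was settled on its values: no value of the first table was other than whole, and all 252 cells of the second equalled the counts times 1 factor. The method that set the factors is not given in the sources used here. All levels reported come from the counts, and the scaled signal served as an alternative.

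Of 304 labelled samples, 13 had no column under their title and were not used here. The labels give each sample a cell, a group and a quality control result, and 252 libraries labelled as passing were kept while 39 labelled as failing were used only in an alternative. Groups were taken from the labels: 31 control cells, 58 cells of the injected side 1 day after kainate, 29 cells 14 days after kainate, 59 GFP cells and 71 Id2 cells. Left out of each comparison were 2 cells of the other side at day 1 and 2 libraries labelled low_DG, which closely match control cells of the same number. No label names an animal, so cells cannot be assigned to animals, each group counts as 1 sample, and no p-value, standard error or number of changed genes was computed from cells. Kainate cells and control cells carry different series of titles, so the group and a possible batch cannot be told apart there. Day 1 and day 14 cells share the K series, but their title numbers do not overlap, so the same holds between the days. The Id2 and GFP cells share 2 sets of titles, IDS up to 95 (43 Id2 and 43 GFP cells) and IDS from 101 (28 and 16 cells).

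Counts were summed over the cells of a group and scaled by the group's total to CPM. The log2 ratio of a comparison was taken after adding 1 CPM, and folds in the text come from CPM without that addition. Exact Poisson intervals for summed counts and exact Clopper-Pearson intervals for shares of cells were set at 95%. Reads carry no molecular identifier named in the labels and are not independent molecules. Poisson intervals thus cover the counting error of reads only, not the spread between cells. Clopper-Pearson intervals treat cells as independent draws, and neither kind covers differences between animals. A fold against a group with 0 reads is given against a floor of 3 counts over the group. For shares of cells, each cell was also thinned at random to 100000 reads, the largest of 5 preset depths that kept at least 90% of the cells of each group, which left out 2 control cells. A gene was measured in a comparison where at least 20% of the cells of a group had a read and a group reached 5 CPM, which gave 9079 genes at day 1, 9469 at day 14, 9823 for day 1 against day 14, 7846 for Id2 against GFP and 8085 for GFP against control.

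Depth differed between groups. Median reads per cell were 1738610 in control cells, 6834546 at day 1, 7615492 at day 14, 3957794 with GFP and 3317227 with Id2, and summed reads were 67177695, 464410001, 259910098, 221823689 and 266116534. Of the 12 highest and 12 lowest genes of all 5 comparisons, the widest counting interval of the higher group's CPM reached 4.05% to either side. Median genes per thinned cell were 3617, 4305, 3924, 3113 and 2709, and median mitochondrial shares 0.823%, 0.201%, 0.319%, 0.295% and 0.281%.

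The groups, comparisons, alternatives, 26 gene lists and rules below were fixed before the data were examined. Named genes are Id1 to Id4 in each comparison, and the 12 highest and 12 lowest genes by the smallest in size of 3 log2 ratios (summed counts, mean over cells, thinned cells). All 3 had to share 1 sign, and at least 40% of the thinned cells of the higher group had to have a read. The ratio from summed counts also had to keep that sign in both title sets for Id2 against GFP. In comparisons with control cells it had to keep it against J-titled controls and against the others. No such check was made for day 1 against day 14. Predicted, Riken, pseudo, mitochondrial and ribosomal protein genes were left out. Some genes that met these rules are not reported here. Up to 4 measured members of each list were also taken by the same ratio, with further genes where a marker or quality fact needed them. Genes set side by side across comparisons in the last parts of the account were picked from these after their values were seen. Each list is given as the median log2 ratio of its measured members where at least 3 were measured, with its percentile among 10000 random lists of the same size drawn from 10 bins of mean expression. A median of at least 0.5 in size, at or below the 2.5th or at or above the 97.5th percentile, was taken as a called list. Setting members with 0 reads in a group at their bound left each printed median as it was. Percentiles describe these libraries and are no test of animals. Oligodendrocyte precursor and endothelial and mural markers had fewer than 3 measured members in each comparison, as did mossy cell markers. Oligodendrocyte markers reached 3 members in 2 comparisons, interneuron markers in 3 and CA pyramidal markers in all 5.

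Alternatives were the mean over cells, thinned cells, TMM factors, median-of-ratios size factors, cells failing quality control included, a pseudocount of 0.1 CPM, no filter on low genes, the deepest 10% of cells left out, the authors' scaled signal, each title set, and GFP cells as the control for kainate. Chosen after seeing the data were the removal of cells with at least 1000 CPM of microglia markers, alone or with GFP cells as the control, of 2 genes that take up reads of ribosomal RNA from the totals, and of cells with over 5% mitochondrial reads. The median log2 ratio of all measured genes was 0.17 at day 1, 0.14 at day 14 and 0.13 for GFP against control, and moved to 0.03, 0.04 and -0.02 with median-of-ratios factors, so ratios of that size are not read as differences. Libraries of a group were compared with each other before they were summed, and 0 pairs of identical libraries were found.

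The procedure was tested on simulated data, in which cells of both groups' depths were drawn from the levels and spread of 1 group and 200 genes were made 2, 4 or 8-fold higher or lower. The log2 ratio of 2.00 planted in 67 of them came out at a median of 1.73 at the depths of day 1 against control, 1.98 at those of day 14, 1.99 for day 1 against day 14, 1.90 for Id2 against GFP and 1.89 for GFP against control. The right sign in all 3 ratios was found for 95.5%, 97.0%, 100%, 100% and 98.5% of these 67, and for 82.1%, 88.1%, 91.0%, 89.6% and 88.1% of the genes planted at 2-fold. Of genes left alone, 9.40%, 13.2%, 10.3%, 7.70% and 9.65% showed at least a 2-fold ratio in all 3, and 0.0738%, 0.280%, 0.304%, 0.0699% and 0.0443% at least an 8-fold one. These shares cover only genes measured in the group that gave the levels (6975 for both days against control), not genes nearly without reads there. Differences between animals or batches were not simulated. Lists of 20 genes left alone had medians of 0.25, 0.40, 0.20, -0.18 and 0.35. Their percentiles among 2000 random lists were 82.55, 96, 84.2, 32.85 and 96.8, the highest close to the limit for a called list. Lists of 20 genes raised 2-fold lay at 100.

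Gene positions come from GENCODE M21. Of 197 named genes, 194 had 1 position, and 10 of them shared at least 20% of their exon bases with another gene (among them C2cd4b, Gpr84, Kcnmb4, Medag, Mt2, Nmb, Sox4 and Tvp23a), whose values are uncertain to that extent. Work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and in R 4.3.3 with edgeR 4.0.16 for TMM factors and DESeq2 1.42.0 for size factors.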

Results

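Single dentate granule cells of the mouse hippocampus, the neurons whose mossy fibre axons run to area CA3, were sampled by Patch-seq, in which the contents of 1 cell are drawn into a patch pipette and sequenced as 1 library. Kainic acid, a glutamate receptor agonist used to provoke seizures, had been injected into the hippocampus as 70 nl of a 5 mM solution. Cells were taken from the injected side 1 day later (58 cells), 14 days later (29 cells, side not labelled) and from mice without an injection (31 control cells). In a second set, cells were taken 1 month after an adeno-associated virus (AAV) carrying either GFP (59 cells) or Id2 (71 cells). Reads counted in genes per cell ranged from 32487 to 7923833 in control cells, 2655957 to 27708910 at day 1, 3316541 to 16659669 at day 14, 312004 to 7596250 with GFP and 780899 to 12639081 with Id2. The labels name no animal, so each group stands as 1 sample and no difference between groups was tested. Values are CPM, a gene's reads scaled by total depth, of the counts summed over a group's cells, and their intervals, at 95%, cover counting error only.

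Id2, an inhibitor of DNA binding that pairs with basic helix-loop-helix factors and keeps them off DNA, was the overexpressed gene and is the gene named in the study's title. Id2 (ENSMUSG00000020644.9, protein coding, GRCm38 chromosome 12, 25093799 to 25097140, minus strand) stood at 127.9 CPM (exact Poisson interval 125.2 to 130.6) in control cells, 1247 CPM (1244 to 1251) 1 day after kainate and 422 CPM (420 to 425) 14 days after kainate. It was thus 9.75-fold higher at day 1 and 3.30-fold higher at day 14 than in control cells. A read of Id2 was found in 38.7% of control cells (exact Clopper-Pearson interval 21.9% to 57.8%), 96.6% of day 1 cells (88.1% to 99.6%) and 82.8% of day 14 cells (64.2% to 94.2%). With every cell thinned to 100000 reads the shares were 34.5%, 93.1% and 79.3%. Id2 stood at 93.2 CPM (91.9 to 94.5) with GFP and 37369 CPM (37346 to 37392) with Id2 virus, a 401-fold difference, and took 3.74% of all reads of the Id2 cells. A read was found in 52.5% of GFP cells (39.1% to 65.7%) and 100% of Id2 cells (94.9% to 100%), or 35.6% and 100% after thinning. Single Id2 cells ranged from 1446 to 105869 CPM. Id2 was higher at both days in each alternative that was tried, between 2.72 and 5.30 on the log2 scale at day 1 and between 0.94 and 2.53 at day 14. The related genes Id1, Id3 and Id4 were below the level set for a measured gene in all 5 comparisons.

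**Figure D1:**
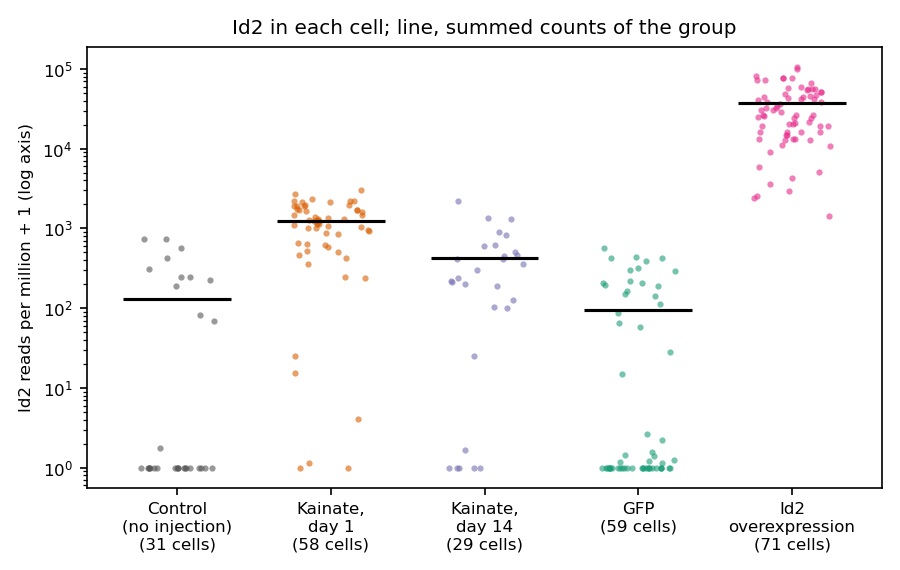
Id2 CPM plus 1 on a log axis, 1 point per cell, in the 5 groups; the horizontal line is the value from the group's summed counts. The line stands at 127.9 CPM in control cells, 1247 at day 1, 422 at day 14, 93.2 with GFP and 37369 with Id2 virus.

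Among the highest genes at 1 day after kainate against control cells, Sorcs3, a sorting receptor of the Vps10 family, stood at 534 against 0.432 CPM, and 89.7% of day 1 cells had a read of it against 3.23% of control cells (79.3% and 3.45% after thinning). Penk, the precursor of enkephalins, stood at 7070 against 38.5 CPM (184-fold), and Npy, the precursor of neuropeptide Y, at 334 against 2.89 CPM (115.8-fold). Anxa2, a calcium-dependent membrane-binding annexin, stood at 200 CPM in 60.3% of day 1 cells and had 0 reads in control cells, at least 4473-fold higher against a floor of 3 counts over the group. Arr3, an arrestin best known from cone photoreceptors, stood at 239 CPM and had 0 reads in control cells (at least 5347-fold higher). The secreted guidance cue Sema3e stood at 128.4 against 1.12 CPM, the perineuronal net proteoglycan Acan at 182 against 4.97 CPM, the metalloprotease Tll1 at 118.3 against 5.25 CPM and the adhesion receptor Adgrl3 at 162 against 9.15 CPM. Smad3, an intracellular carrier of activin and TGF-beta signals, stood at 101.9 against 0.968 CPM (87.1 CPM in GFP cells), the transcription factor Npas2 at 56.1 against 0.670 CPM and the membrane protein gene Tvp23a at 88.9 against 4.93 CPM (111.9 CPM in GFP cells).

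The lowest genes at day 1 included Cenpa, a centromeric histone, with 0 reads in day 1 cells against 212 CPM in control cells (at least 32805-fold lower). Kcnip2, a subunit of A-type potassium channels, stood at 24.2 against 263 CPM (10.9-fold lower), and Mmd2 at 31.2 against 322 CPM. Sparc, a secreted matrix glycoprotein, stood at 17.9 against 451 CPM and Chrd, which codes for the BMP antagonist chordin, at 9.43 against 121.1 CPM. The polo-like kinase Plk5 stood at 8.97 against 157 CPM, the cyclin-dependent kinase Cdk14 at 21.1 against 324 CPM, Apaf1, the core of the apoptosome, at 4.70 against 86.5 CPM and the malic enzyme Me3 at 4.91 against 129 CPM. Palmd (3.52 against 102.2 CPM), Lcorl (9.76 against 326 CPM) and Rab21 (1.82 against 35.3 CPM) completed the 12.

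Among the lists fixed beforehand, neuropeptides and granins had a median log2 ratio of 1.37 at day 1, above all 10000 random lists of matched expression, with 10 of 13 measured members higher, but 0.41, below the limit for a called list, with genes of any level included. Pdyn, the precursor of dynorphins, stood at 361 against 55.6 CPM. Lists of the neuron's electrical and receptor genes lay lower. Potassium, sodium, calcium and HCN channel genes had a median of -0.69 (38 of 55 lower), though -0.24 against J-titled controls, among them Scn3b, a sodium channel subunit, at 36.2 against 264 CPM and Kcnmb4 at 7.74 against 62.0 CPM. Glutamate receptor genes had a median of -0.74 (14 of 18 lower), but Grm7 stood at 366 against 77.8 CPM and Grm8 at 61.7 against 0.104 CPM. GABA receptor genes had a median of -0.74 (9 of 11 lower), with Gabra5 at 148 against 388 CPM and Gabbr1 at 66.9 against 147 CPM. Axon guidance ligands and receptors had a median of -0.89 (22 of 35 lower), with Efnb2 at 3.82 against 31.5 CPM, but this median was -0.33 without the deepest 10% of cells of each group. Dentate granule cell markers had a median of -1.26 (10 of 15 lower), or -0.62 with genes of any level included, with the calcium buffer Calb1 at 411 against 1249 CPM, Tdo2 at 8.18 against 114.1 CPM and Pdzd2 higher, at 115.7 against 26.9 CPM.

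Activity-regulated genes had a median of -0.05, with 20 of 40 members on either side. Of them, Inhba, which codes for an activin subunit, stood at 727 against 46.4 CPM and the early transcription factor Npas4 at 51.03 against 282 CPM. Axon growth-associated genes had a median of 0.49 at the 95.9th percentile of random lists, short of the upper limit set for a called list, and of -0.011 with the scaled signal. Sox11 stood at 673 against 131 CPM and Gap43, a growth cone protein, at 66.4 against 6.83 CPM. Synaptic adhesion genes had a median of -0.10 (0.52 without microglia-rich cells), BMP, activin and TGF-beta genes -0.08 (mean 0.95, and a median of 1.56 against the controls with other titles). The BMP, activin and TGF-beta list as fixed also holds the sorting receptor gene Sorcs3, whose ratio of 8.55 was its largest and raises that mean. Medians were -0.38 for Wnt genes (mean 0.28), -0.40 for Id and basic helix-loop-helix regulators (mean 0.24) and -0.39 for immature neuron genes. Of these regulators, Tcf12, a partner of Id proteins, stood at 75.6 against 7.52 CPM. Inflammatory genes had a median of 0.78 (95.0th percentile), with Stat3 at 313 against 65.9 CPM, but 1.99 without cells rich in microglia markers and 3.19 against GFP cells. Medians were 0.38 for heat shock and unfolded protein response genes and for nuclear-encoded respiratory chain genes (the latter slightly below 0 against GFP cells), 0.45 for ribosomal protein genes and -0.89 for mitochondrial-genome genes.

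The control cells carried more RNA of microglia, the brain's resident macrophages, than the day 1 cells. The microglia list had a median of -2.62 at day 1, all 13 measured members were lower, and its summed level was 3643 CPM in control cells against 779 CPM at day 1. Of the other cell types, astrocyte markers had a median of -0.41, CA pyramidal cell markers 0.03 (2.21 against GFP cells and -1.13 with genes of any level included) and interneuron markers -0.03 (mean 0.90, 3 measured). With GFP cells as the control the microglia list turned to 2.14, and Tvp23a (-0.33), Sparc (0.14) and Gabbr2 (0.26) changed sign. Without cells at or above 1000 CPM of microglia markers the day 1 ratio of Id2 was 5.30.

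At 14 days after kainate, neuropeptides were again among the highest genes and transcripts of immune defence stood beside them. Npy stood at 1796 against 2.89 CPM (622-fold), in 65.5% of day 14 cells against 6.45% of control cells (58.6% and 6.90% after thinning). Penk stood at 7604 against 38.5 CPM (198-fold) and Sorcs3 at 171 against 0.432 CPM (396-fold). The chemokine gene Ccl5 stood at 668 against 1.67 CPM (401-fold), in 62.1% of cells against 3.23%. Gpr84, a fatty acid receptor of myeloid cells, stood at 155 CPM, the glycoprotein gene Gpnmb at 112.3 CPM and the interferon-induced gene Xaf1 at 88.2 CPM, each with 0 reads in control cells (at least 3476-fold, 2514-fold and 1975-fold higher). Medag (149 CPM), Sowahb (176 CPM) and Mtx3 (67.2 CPM) also had 0 control reads, and Nell1, which codes for a secreted protein, stood at 215 against 1.40 CPM and the exoribonuclease gene Pnpt1 at 164 against 1.43 CPM.

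The lowest genes at day 14 included Npas4, the activity-dependent transcription factor, at 3.37 against 282 CPM (83.8-fold lower), and Camk2n1, an inhibitor of the synaptic kinase CaMKII, at 8.95 against 128.2 CPM (14.3-fold lower). Plk5 stood at 1.44 against 157 CPM, Cdk14 at 4.07 against 324 CPM and Lcorl at 0.623 against 326 CPM. Cygb, which codes for cytoglobin, stood at 0.00385 CPM (1 read) against 48.6 CPM. Phxr4 (0.442 against 45.2 CPM), Sap130 (2.74 against 48.3 CPM), Zdhhc1 (7.91 against 110.6 CPM) and Zfp653 (5.52 against 75.5 CPM) were lower too. Rn18s-rs5, a gene whose sequence matches ribosomal RNA, stood at 1166 against 36508 CPM, and Lars2, which takes up reads of the same kind, at 573 against 5812 CPM. These 2 genes were also lower at day 1 (3888 and 1498 CPM).

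Neuropeptides and granins had a median of 1.30 at day 14, above all random lists, with 9 of 13 higher. Cartpt, a peptide precursor, stood at 2453 against 43.9 CPM in 86.2% of cells against 6.45%, and Trh, the precursor of thyrotropin-releasing hormone, at 380 CPM against 0 reads (at least 8515-fold higher). Activity-regulated genes had a median of -0.52 (28 of 41 lower), with Arc, a regulator of synaptic strength, at 253 against 1750 CPM and Ptgs2 at 43.8 against 384 CPM. Glutamate receptor genes had a median of -0.76 (13 of 17 lower), with Gria1 at 209 against 607 CPM, the kainate receptor gene Grik3 at 0.569 against 45.3 CPM, and Gria4 higher, at 165 against 31.5 CPM. Granule cell markers had a median of -1.33 (13 of 15 lower), or -0.78 with genes of any level included, with Tdo2 at 1.84 against 114.1 CPM, Rfx3 at 123.3 against 657 CPM and Stxbp6 at 84.2 against 340 CPM. Immature neuron genes had a median of -0.83 (7 of 9 lower), with Dpysl3 at 56.8 against 220 CPM, but 0.96 against the 9 controls whose titles do not start with J. Nuclear-encoded respiratory chain genes had a median of 0.58 (71 of 80 higher), with Ndufs1 at 314 against 87.7 CPM, but 0.15 against GFP cells.

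Channel genes had a median of -0.34 at day 14 (0.093 against GFP cells) and synaptic adhesion genes -0.25. Axon guidance genes had a median of -0.13 (lower, and over 0.5 in size, against GFP cells) and GABA receptor genes -0.04 (0.6885 against J-titled controls). Axon growth genes had a median of 0.09, BMP, activin and TGF-beta genes 0.25, Wnt genes -0.21 (0.53 against the controls with other titles) and Id and helix-loop-helix regulators 0.79 (96.4th percentile, but -0.36 against GFP cells and -0.63 without cells rich in microglia markers). Within them, the adhesion gene Cntn4 stood at 191 CPM against 0 reads (at least 4279-fold higher) and Kirrel3 at 20.6 against 206 CPM. The guidance genes Sema3a and Slit2 lay in opposite directions, Sema3a at 42.1 against 0.0298 CPM (2 reads) and Slit2 at 0.00770 (2 reads) against 36.8 CPM. The activin receptor gene Acvr1c stood at 50.3 against 0.551 CPM. Heat shock genes had a median of 0.08 and ribosomal protein genes -0.10, the latter of the other sign against the controls with other titles. Mitochondrial-genome genes had a median of -0.19, or -0.89 without the 1 day 14 cell with over 5% of reads in them, but of the other sign against GFP cells.

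Inflammatory genes had a median of 2.51 at day 14, above all random lists, and 18 of 19 measured members were higher. The cytokine gene Il1b stood at 222 CPM against 0 reads (at least 4979-fold higher) and the interferon-induced gene Ifit1 at 154 against 0.164 CPM. Microglia markers lay with them, with a median of 0.85, 12 of 14 members higher and a summed level of 6690 CPM against 3643 CPM. C1qc stood at 1039 against 283 CPM, Ctss at 1141 against 495 CPM and Apoe, abundant in astrocytes and in reactive microglia, at 3942 against 297 CPM. Astrocyte markers had a median of 0.40 (mean -0.12), but -0.56 against the controls with other titles and -0.40 without microglia-rich cells. CA pyramidal cell markers had a median of -0.11 (mean 0.24), but 2.64 against the controls with other titles, 1.90 against GFP cells and -1.13 without microglia-rich cells. Medians were 0.68 for interneuron markers (3 measured) and 0.99 for oligodendrocyte markers (3 measured). Without cells at or above 1000 CPM of microglia markers, which left 9 day 14 and 14 control cells, the inflammatory median was 0.24 and that of microglia markers -0.35. In those cells Ccl5 had a log2 ratio of 2.10, Gpr84 and Il1b of 0.00, Xaf1 of 3.60, Ifit1 of 7.66 and Apoe of -3.37. Genes were not filtered again there, so a ratio of 0.00 can mean no reads in either group rather than equal levels.

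**Figure D2:**
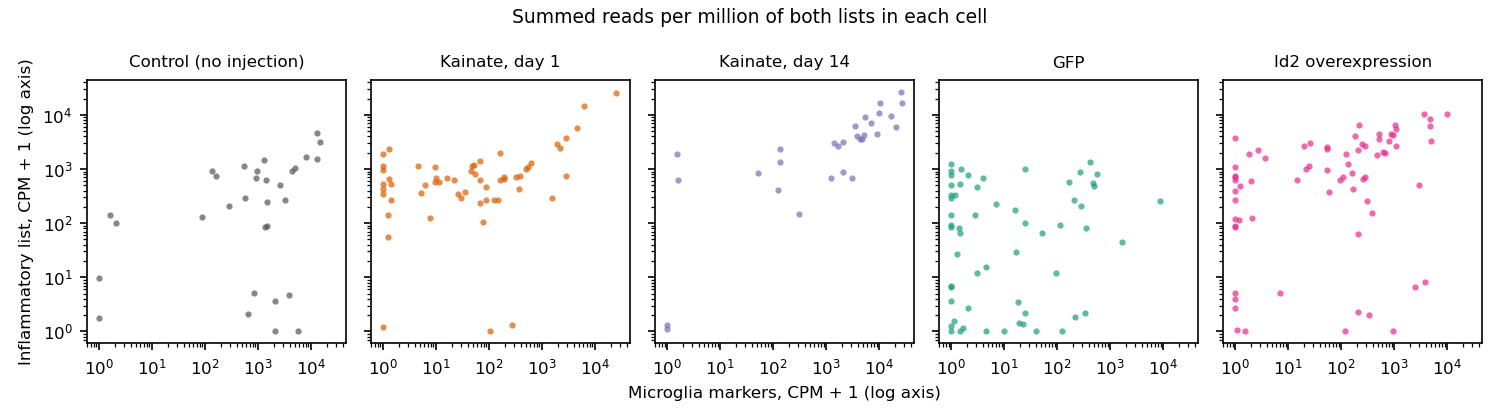
Each point is 1 cell of the 5 groups, with the summed CPM plus 1 of the microglia list on the x axis and of the inflammatory list on the y axis, both log axes. At least 1000 CPM of microglia markers was reached by 54.8% of control cells, 13.8% at day 1, 68.97% at day 14, 3.39% with GFP and 15.5% with Id2 virus.

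With day 1 and day 14 cells set against each other, Inhba stood at 727 CPM at day 1 against 46.6 CPM at day 14, Ptgs2, the inducible cyclooxygenase, at 650 against 43.8 CPM, and Synpo, an actin-binding protein of dendritic spines, at 351 against 19.4 CPM. The linker histone gene Hist1h1c stood at 254 against 9.41 CPM, Pla2g7 at 122.03 against 6.60 CPM, Klhl32 18.5-fold higher than its 5.72 CPM at day 14 and Sertm1 at 98.01 against 3.63 CPM. The immunoglobulin superfamily members Igsf3 (77.8 against 2.10 CPM) and Igsf9b (84.9 against 2.05 CPM), Ralgapb (69.3 against 2.65 CPM), the kinase anchor Akap7 (49.7 against 4.03 CPM) and Neu2 (31.8 against 1.87 CPM) were also higher at day 1. Higher at day 14 were Cartpt (2453 against 48.8 CPM), the interferon-induced genes Irf7 (410 against 3.996 CPM), Ifitm3 (225 against 2.06 CPM), Xaf1 (88.2 against 0.0883 CPM) and Ifi27l2a (211 CPM against 1 read), and Ccl5 (668 against 2.00 CPM). Cst7 (346 against 12.6 CPM), the protease gene Ctsh (216 against 5.78 CPM), Lcp2 (189 against 4.64 CPM), Sulf2 (89.5 against 0.999 CPM), Apobec3 (68.8 against 1.008 CPM) and Lst1 (46.6 against 0.168 CPM) lay on the same side. Id2 was 2.96-fold higher at day 1 than at day 14. Title numbers of both days do not overlap, so day and a possible batch cannot be told apart in this comparison.

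In this comparison, with positive medians for higher at day 1, ribosomal protein genes had a median of 0.56 (66 of 78 higher at day 1), granule cell markers 0.58, immature neuron genes 0.88, Id and helix-loop-helix regulators 0.69 (mean -0.25), activity-regulated genes 0.45 and heat shock genes 0.45. Inflammatory genes had a median of -2.03 (18 of 19 higher at day 14), microglia markers -3.22 (14 of 14), mitochondrial-genome genes -0.88, GABA receptor genes -0.62, astrocyte markers -0.69, interneuron markers -1.87 and oligodendrocyte markers -1.33 (3 measured each for the last pair). Medians between -0.35 and 0.35 were found for channel genes (-0.32), respiratory chain genes (-0.23), BMP, activin and TGF-beta genes (-0.12), neuropeptides (-0.11), axon growth genes (-0.11, mean 0.19), glutamate receptors (-0.10), synaptic adhesion (-0.09, mean 0.01), Wnt (-0.01, mean 0.21), axon guidance (0.08, mean -0.35) and CA pyramidal markers (0.32, mean -0.98). Without cells rich in microglia markers the inflammatory median was 0. Such a value can mean no reads of a gene at either day rather than equal levels. In the same cells GABA receptors (0.22), astrocyte markers (0.60) and mitochondrial-genome genes (0.082) changed sign, and Ifitm3 (1.03), Cst7 (1.03) and Apobec3 (0.36) turned towards day 1. With genes of any level included, astrocyte (0.025) and interneuron (0.0062) markers changed sign as well. Without the 1 day 14 cell with over 5% mitochondrial reads the mitochondrial median was -0.21 and that of astrocyte markers 0.44.

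Among the highest genes after 1 month of Id2 overexpression, Ifit1, an interferon-induced antiviral gene, stood at 513 against 0.131 CPM in GFP cells, with a read in 57.7% of Id2 cells (45.4% to 69.4%) against 23.7% of GFP cells (13.6% to 36.6%), or 40.8% against 0% after thinning. Irf9, part of the transcription complex that interferon activates, stood at 181 against 18.5 CPM (9.79-fold), and the cytokine-activated factor Stat3 at 155 against 4.96 CPM (31.2-fold). B2m, the light chain of MHC class I, stood at 188 against 41.04 CPM (4.59-fold). Phgdh, the first enzyme of serine synthesis, stood at 213 against 20.3 CPM, the transcription factor gene Bcl11a at 126.8 against 39.7 CPM, the copper chaperone Atox1 at 82.7 against 21.3 CPM and the metallothionein Mt2 at 73.4 against 25.8 CPM. Exoc1, a subunit of the exocyst that tethers vesicles to the membrane, stood at 173 against 58.9 CPM and Pigp at 71.1 against 21.99 CPM.

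Among the lowest genes with Id2, Grm2, the presynaptic glutamate receptor of mossy fibres, stood at 27.1 against 218 CPM (8.05-fold lower), and Tle1, a corepressor that works with Hes-type helix-loop-helix repressors, at 31.95 against 248 CPM (7.75-fold lower). The guidance cue Slit1 stood at 76.05 against 401 CPM (5.27-fold lower), the synaptic kinase anchor Akap5 at 15.5 against 78.6 CPM (5.09-fold lower) and the neuronal leucine-rich repeat gene Lrrn3 3.96-fold below its 463 CPM in GFP cells. Smoc2, a matrix protein, stood at 35.1 against 208 CPM, with a read in 9.86% of Id2 cells against 62.7% of GFP cells (9.86% and 54.2% after thinning). C2cd4b (79.5 against 476 CPM), Ptgs2 (39.7 against 206 CPM), Cdc40 (49.7 against 178 CPM), Fam193b (29.9 against 107.5 CPM), the metalloprotease Adamts20 (20.8 against 71.5 CPM) and Ypel1 (13.4 against 53.9 CPM) completed the 12. Each of these highest and lowest genes has 1 direction in both sets of titles, as the naming rule requires.

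Inflammatory genes had a median of 4.48 with Id2, above all random lists, with 6 of 8 measured members higher, among them Irf1 at 178 against 0.284 CPM and Irf7 at 113.5 against 0.243 CPM. Single Id2 cells differed widely, with sums over the whole list from 0 to 10222 CPM. Microglia markers lay with the inflammatory genes, with a summed level of 612 against 182 CPM and a median of 1.78 over 4 measured members, such as C1qa at 85.1 against 16.8 CPM. Astrocyte markers had a median of 0.51 (7 of 8 higher), with Apoe at 240 against 35.5 CPM. Among the 33 Id2 and 44 GFP cells below 100 CPM of microglia markers, Ifit1 stood at 381 against 0.0672 CPM and Stat3 at 45.8 against 6.72 CPM, but Serpina3n at 31.8 against 76.6 CPM and Cxcl12 at 85.2 against 88.7 CPM. Granule cell markers had a median of -0.66 (15 of 17 lower), with Npnt at 7.23 against 60.6 CPM, Tdo2 at 22.03 against 130 CPM, the channel gene Trpc6 at 65.3 against 175 CPM and Lct at 0.00752 (2 reads) against 84.3 CPM. Id and helix-loop-helix regulators had a median of 0.67 (8 of 9 higher, Id2 among them), with Bhlhe40 at 459 against 234 CPM and Neurod1 at 156 against 98.04 CPM, but 0.08 with genes of any level included. Mitochondrial-genome genes had a median of 1.45 (12 of 12 higher), but 0.39 without the 3 cells with over 5% of reads in them (2 Id2 and 1 GFP) and -0.22 in the title set of higher IDS numbers.

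The median of all 7846 measured genes was -0.10. Activity-regulated genes had a median of -0.24, with Homer1, a synaptic scaffold gene, at 424 against 1107 CPM and Nr4a2 at 161 against 583 CPM. Axon guidance genes had a median of -0.22, with Slit2 at 70.7 against 22.3 CPM and Ntng2 at 0.586 against 12.4 CPM. Medians were -0.05 for axon growth genes, where Stmn2, a microtubule regulator of growing axons, stood at 212 against 55.5 CPM, -0.18 for synaptic adhesion genes, -0.11 for channels, -0.09 for glutamate receptors and -0.35 for GABA receptors (0.16 with the mean over cells, 0.14 with thinned cells and 0.24 with the scaled signal). BMP, activin and TGF-beta genes had a median of -0.41, with Acvr1c at 0.331 against 35.9 CPM and Fstl1 at 2.19 against 23.3 CPM. Neuropeptides and granins had a median of -0.31, Wnt genes 0.19 (-0.54 in the title set of lower IDS numbers and 0.82 in that of higher ones), immature neuron genes 0.40 (mean 0.00, and a median of -0.24 with genes of any level included). CA pyramidal markers had a median of -0.19, heat shock genes -0.03, ribosomal protein genes 0.03 and respiratory chain genes -0.13.

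**Figure D3:**
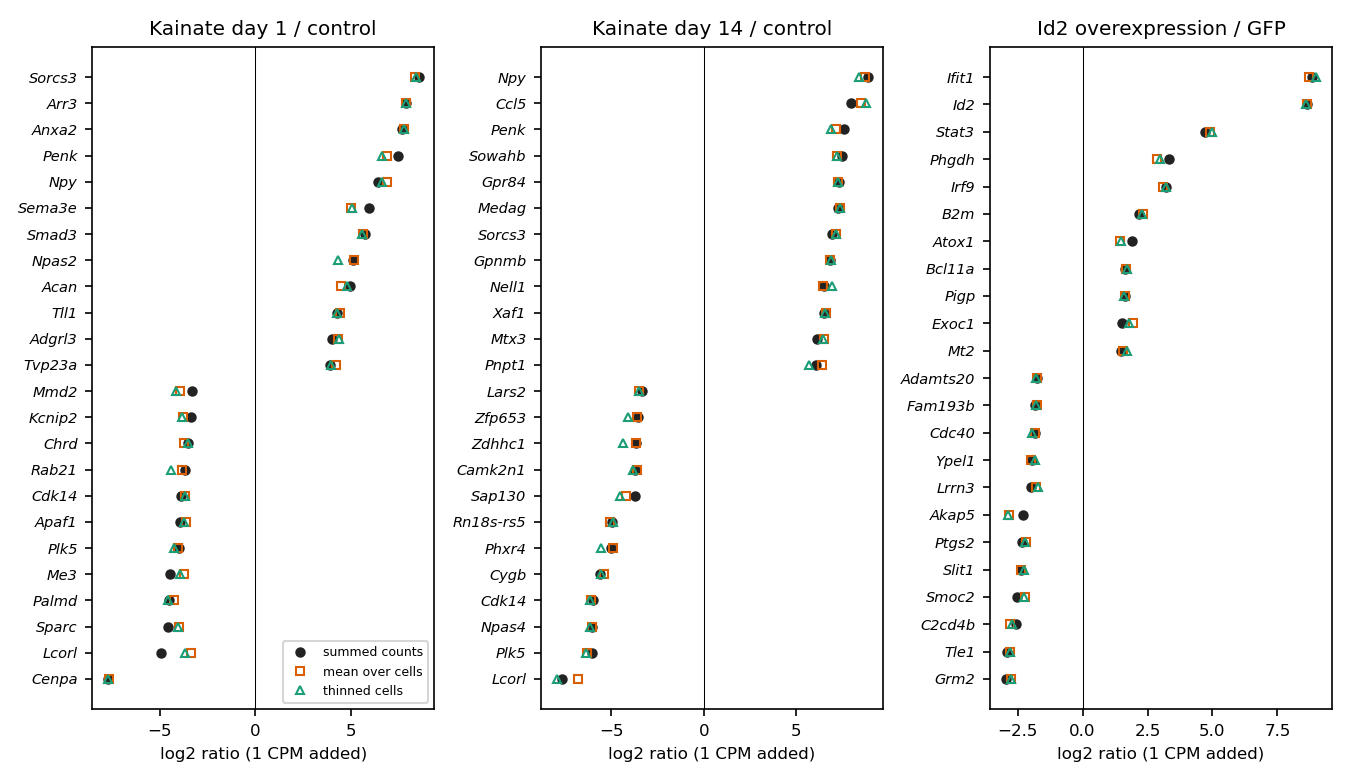
Genes among the 12 highest and 12 lowest of 3 comparisons on the log2 scale, from summed counts (black), from the mean over cells (orange squares) and from cells thinned to 100000 reads (green triangles). The 3 estimates share 1 sign for each gene, as the naming rule requires.

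**Figure D4:**
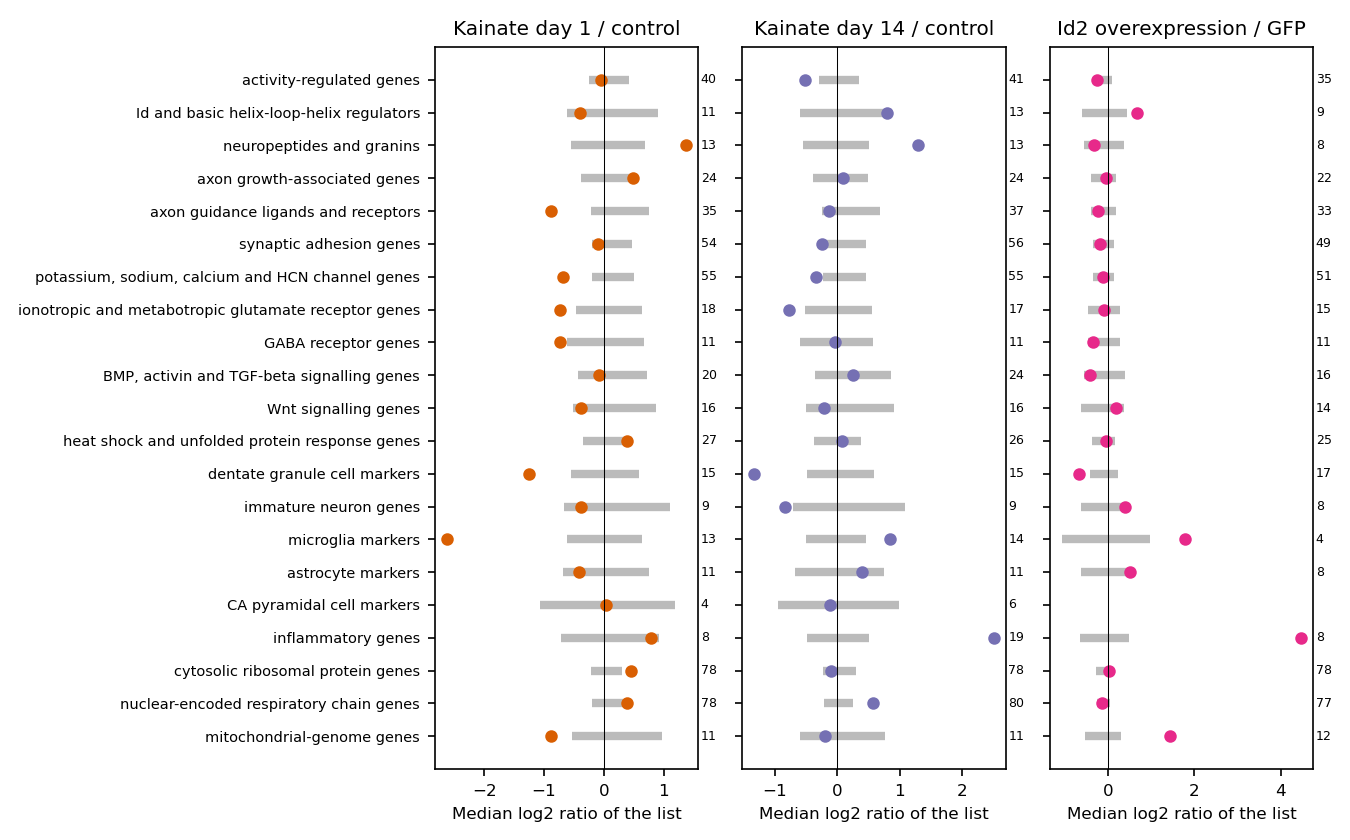
Median log2 ratio of each fixed list with more than 3 measured members (points) in 3 comparisons. Grey bars give the central 95% of 10000 random lists of matched expression, and the number of measured members stands at the right. Neuropeptides lie at 1.37 and 1.30 after kainate, granule cell markers at -1.26, -1.33 and -0.66.

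Whether Id2 overexpression and kainate moved the same genes was asked across genes, since these comparisons share no cells. Log2 ratios of Id2 overexpression had a Spearman correlation of 0.03 with those of day 1 over 7453 genes and 0.06 with those of day 14 over 7486 genes (Pearson 0.03 and 0.10), where genes are not independent replicates. Simulated genes left alone had ratios with quartiles of -0.48 and 0.31 for Id2 against GFP and -0.47 and 0.55 for day 1. Such noise draws a correlation towards 0, so these low values cannot show that different genes moved. Single genes illustrate both outcomes. Stat3 was higher in all 3 comparisons (log2 ratios of 4.71 with Id2, 2.23 at day 1 and 1.04 at day 14), Slit1 lower in all 3 (-2.38, -2.22 and -3.05) and Tdo2 lower in all 3 (-2.50, -3.65 and -5.34). Penk, far higher after kainate, had a ratio of -2.27 with Id2, and Sorcs3 one of -0.45.

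The 2 sets of control cells differed from each other in microglial transcripts above all. In GFP cells the microglia list had a median of -4.39 against control cells (13 of 13 lower), with Tyrobp at 9.76 against 428 CPM, C1qb at 25.6 against 521 CPM, Aif1 at 6.27 against 260 CPM and Fcer1g at 0.00451 (1 read) against 223 CPM. Ctsz, Ucp2, Camk1, Sc5d, Brf1 and Ccdc184 were lower in GFP cells as well, at 6.36, 8.95, 9.39, 12.5, 8.88 and 6.87 CPM against 273, 265, 179, 191, 87.6 and 61.9 CPM, and the Y-linked gene Eif2s3y stood at 20.8 against 233 CPM. Higher in GFP cells were Myc (225 against 19.6 CPM), the sodium channel subunit Scn2b (58.1 against 6.45 CPM), Hlf (85.1 against 10.4 CPM), Setd7 (96.9 against 13.03 CPM), Clasp2 (175 against 31.6 CPM), Glrx2 (101.8 against 16.4 CPM) and Cxx1c (100 against 9.97 CPM). Extl1 (268 against 51.8 CPM), Ttc39c (166 against 33.6 CPM), Sugp1 (136 against 21.97 CPM), Lin37 (124.7 against 24.6 CPM) and Msto1 (89.4 against 19.9 CPM) completed that side. Smad3 and Acvr1c, high after kainate, were high in GFP cells too (87.1 against 0.968 CPM and 35.9 against 0.551 CPM).

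By list, the GFP cells lay lower than control cells in inflammatory genes (median -1.98), mitochondrial-genome genes (-1.06) and astrocyte markers (-1.04), and higher in respiratory chain genes (0.51). Without cells rich in microglia markers the inflammatory median was 0.12 and that of mitochondrial-genome genes -0.29. Medians of the other lists were 0.45 for granule cell markers, 0.39 for immature neuron genes, 0.30 for axon guidance, 0.18 for activity-regulated and for axon growth genes, 0.06 for ribosomal proteins and for BMP, activin and TGF-beta genes, -0.02 for synaptic adhesion (mean 0.04) and -0.06 for channels. Further medians were -0.15 for heat shock genes (mean 0.07), -0.18 for neuropeptides, -0.20 for GABA receptors, -0.29 for Id and helix-loop-helix regulators, -0.37 for Wnt genes, -0.40 for glutamate receptors and -0.49 for CA pyramidal markers. Id2 was 1.37-fold lower in GFP cells than in control cells, but higher by 1.59 on the log2 scale without cells rich in microglia markers.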

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

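The tests of this part that select cells by microglia markers were chosen only after the results were seen, and the tests by control cells, depth and title set, planned as alternatives, were set against these explanations after the results were seen.

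Cells from the side opposite the injection at day 1, labelled as their own group of 2 cells and used in no comparison, held summed levels of several genes above those of control cells. Id2 stood at 204 CPM there against 127.9 CPM, but its single cells (149.7 and 395.9 CPM) lay within the range of single control cells, which reached 734.7 CPM. Sorcs3 stood at 111.5 CPM against 0.432 CPM and Anxa2 at 570 CPM against 0 reads. Penk stood at 1698 against 38.5 CPM, from 52.7 CPM in 1 cell and 2164 CPM in the other, Npy at 4758 against 2.89 CPM, Sema3e at 130 against 1.12 CPM, Acan at 75.4 against 4.97 CPM and Adgrl3 at 189 against 9.15 CPM. Arr3 had 0 reads in both cells, and Smad3, Npas2, Tll1 and Tvp23a had reads in 1 of them. The microglia list lay on opposite sides at the 2 times against control cells. Its median was -2.62 over 13 genes at day 1 and 0.85 over 14 genes at day 14. Against GFP cells both medians lay on 1 side (2.14 and 5.34), as they did without microglia-rich cells (-0.84 and -0.35). Those cells were left out by the same markers, so the last values cannot show how the list differs between the days. The difference was not tested.

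Inflammatory genes were higher 14 days after kainate, with a median log2 ratio of 2.51. Against GFP cells the median was 6.68, so the direction was the same against either control set. GFP cells themselves lay below control cells in inflammatory genes (-1.98) and microglia markers (-4.39). A larger value was thus set beforehand, and this change of control cannot weigh the choice of control cells as a cause. Without cells at or above 1000 CPM of microglia markers the median against control cells was 0.24 over 9 day 14 and 14 control cells. RNA from microglia in the collected cytosol may thus account for part of the pattern, with Il1b at 0.00 there but Ifit1 at 7.66. With so few cells left, members without reads in either group can also draw the median towards 0. C1qc (1039 CPM), Ctss (1141 CPM) and Apoe (3942 CPM) were among the most abundant of such transcripts at day 14, and no sort or gate that would remove them is named in the labels. A response of the granule cells themselves stays open, since the median against GFP cells without such cells was 1.10 over only 9 and 57 cells.

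Inflammatory genes were also higher with Id2 overexpression, with a median of 4.48. Among cells below 100 CPM of microglia markers (33 Id2 and 44 GFP cells) the median was 3.53, which argues against RNA from microglia as the whole cause. The lower median of both title sets was 4.23, which argues against cells of 1 title set alone. Smaller batches inside a title set are not excluded by this split. Within the lower IDS numbers, in title order, Id2 cells 1 to 6 held 0 to 630 CPM of the list in sum. Id2 cells 22 to 27 held 2257 to 10217 CPM. Within the higher IDS numbers, Id2 cells 44 to 65 held 0 to 4305 CPM and cells 66 to 71 held 0 to 505 CPM. Cells 44 to 65 held 3571 to 32306 CPM of Id2, and cells 66 to 71 held 46145 to 81823 CPM. All stretches were picked after the values were seen. A read of Ifit1 in 57.7% of Id2 cells could reflect an effect of Id2 or a difference in vector dose, animals or batch between the groups. These cannot be told apart because no further vector group or animal label exists here to set against them. The cells with the most Id2 (105869, 100770 and 81823 CPM) held 62.6, 635 and 0 CPM of the inflammatory list in sum. Those with the highest sums (10222, 10217 and 8384 CPM) held 23959, 20157 and 42097 CPM of Id2. In these cells the most Id2 did not go with the highest sums, which was not tested over all cells.

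Granule cell markers were lower at day 1 (-1.26), at day 14 (-1.33) and with Id2 (-0.66), though with genes of any level included the kainate medians shrank to -0.62 and -0.78. More RNA from microglia cannot be the whole cause at day 1, since microglia markers were lower there (-2.62). The same holds with Id2, where the median without cells rich in microglia markers was -0.85. At day 14 that median was -1.004, but over only 9 day 14 and 14 control cells, too few to exclude this cause. Depth per cell cannot be the whole cause either, since thinned cells gave -1.004, -0.82 and -0.64. Against GFP cells the medians were -1.44 at day 1 and -1.55 at day 14, so the direction was the same against either control set. GFP cells themselves lay at 0.45 against control cells, so lower values were set beforehand and cannot weigh the choice of control cells further. At day 1, 5 of 15 members were not lower: Prox1 (0.19), Rasl10a (0.41), Trpc6 (0.04), Npnt (0.10) and Pdzd2 (2.06). Some kept libraries held few reads of the list, with sums of 0.779 CPM in control cell 9, 11.4 CPM in day 1 cell 48 and 10.5 CPM in Id2 cell 37. Day 1 cell 13 held 164.5 CPM of it beside 25357 CPM of microglia markers. Such libraries entered the group sums as granule cells. Weaker expression of part of the granule cell programme after kainate and with Id2 may underlie the pattern, as a hypothesis found on the same cells. Counts of these transcripts within single granule cells of several labelled animals per group could weigh it, while for kainate title series and group remain confounded.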

How the results depend on the processing

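Values are log2 ratios, for lists as medians, and the cause of a difference between settings was not tested unless stated. Tests without microglia-rich cells, without cells rich in mitochondrial reads and without the 2 genes that take up ribosomal RNA reads were chosen only after the results were seen. Id2 kept its direction at day 1, at day 14, for day 1 against day 14 and for Id2 against GFP under each alternative. Of its 67 alternative values over all 5 comparisons, 34 lay further from the first value than counting error (or than 0.5 for day 1 against day 14 and GFP against control) and 1 changed sign. Both Spearman correlations across genes stayed between 0.01 and 0.06 in all 32 values. Of 1584 alternative list medians, 1468 lay no further from the first value than 0.5 of the width of the central 95% of random lists, and 13 medians of called lists changed sign. Of 2988 alternative values of named genes, 2298 lay within 0.5 of the first value, 673 further away and 17 on the other side of 0. Taking out cells rich in microglia markers leaves few cells (9 at day 14, 14 controls), and the controls with other titles are 9 cells. Genes were not filtered again in such subsets, so a value of 0 can mean no reads in either group. The alternative without libraries titled IDSS, and the planned comparison of such pairs, were not run because no column carries those titles. No paired analysis was possible because the labels pair no cells between the 5 compared groups. Depth limits the control cells most, at 32487 reads in the shallowest.

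With the mean over cells, ratios were -1.865 for microglia markers at day 1, 1.76 for Id2 and 0.34 for the respiratory chain at day 14, -0.41 for axon guidance at day 1 against day 14, 0.16 for GABA receptors and 0.95 for the mitochondrial genome with Id2. Thinned cells gave 3.35 for Id2 at day 1, 1.81 for Id2 at day 14, 8.61 for Id2 and 0.14 for GABA receptors with Id2, and -3.46 for microglia in GFP against control, with the median log2 ratio, microglia markers, 1 day after kainate against control, at -1.985. For Id2 at day 1 and at day 14, TMM factors gave 3.20 and 1.63, and median-of-ratios factors 3.12 and 1.61. The Id2 log2 ratio, Id2 overexpression against GFP, came to 8.66 and 8.68 with these. Id2 came to 2.72 at day 1 and 1.15 at day 14 with failed cells included, and to 3.22 and 1.655 without the 2 genes that take up ribosomal RNA reads.

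Without the deepest 10% of cells, Id2 came to 3.01, 1.63 and 8.43, axon guidance at day 1 to -0.33, and activity-regulated genes and interneuron markers at day 1 against day 14 to 0.074 and -0.55. The scaled signal gave 3.12, 1.45 and 8.73 for Id2, -0.011 for axon growth at day 1, and -0.89 for activity-regulated genes, -0.49 for ribosomal proteins and 0.21 for the respiratory chain at day 14. It also gave -0.40 for axon guidance at day 1 against day 14, 0.11 for synaptic adhesion and 0.24 for GABA receptors with Id2, and -0.27 for axon growth in GFP against control. A pseudocount of 0.1 CPM gave 5.36 for inflammatory genes with Id2.

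Against J-titled controls, Id2 came to 3.51 at day 1 and 1.945 at day 14, channels at day 1 to -0.24 and GABA receptors at day 14 to 0.6885. Against the other controls, day 1 values were 2.88 for Id2, 1.56 for BMP and activin genes, -1.25 for astrocytes, 0.7647 for ribosomal proteins, 0.65 for the respiratory chain and 0.61 for Ephb2, which changed sign. At day 14 they gave 1.315 for Id2, 0.76 for neuropeptides, 0.53 for Wnt, 0.96 for immature neurons (sign changed), 1.57 for microglia, -0.56 for astrocytes, 2.64 for CA markers, 6.37 for inflammatory genes and 0.17 for ribosomal proteins, and 0.8251 for the median log2 ratio, nuclear-encoded respiratory chain genes, 14 days after kainate against control. GFP against these controls gave 0.51 for activity-regulated genes, 0.95 for BMP and activin, 0.19 for heat shock and 0.43 for ribosomal proteins.

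With GFP cells as the control, signs changed at day 1 for microglia (2.14), Gabbr2 (0.26), Sparc (0.14), Trem2 (3.04) and Tvp23a (-0.33), and at day 14 for Smad3 (-1.65). Other day 1 values were 3.73 for Id2, 2.21 for CA markers and 3.19 for inflammatory genes, and -0.077 for the median log2 ratio, nuclear-encoded respiratory chain genes, 1 day after kainate against control. Other day 14 values were 2.17 for Id2, -1.13 for activity-regulated genes, -0.36 for Id and helix-loop-helix regulators, -0.77 for axon guidance and 0.093 for channels. Microglia came to 5.34 there, CA markers to 1.90, inflammatory genes to 6.68, the respiratory chain to 0.1456 and the mitochondrial genome to 1.15.

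Without microglia-rich cells, the Id2 log2 ratio, 1 day after kainate against control, was 5.295, with 0.52 for synaptic adhesion, -0.84 for microglia, 1.99 for inflammatory genes and 0.95 for ribosomal proteins. At day 14 signs changed for microglia (-0.35), Apoe (-3.37), Ctss (-0.25) and Egr3 (0.64), and for the C1qc log2 ratio, 14 days after kainate against control, at -0.086. Id2 came to 2.53 there, Id and helix-loop-helix regulators to -0.63, glutamate receptors to -1.66, astrocytes to -0.40, CA markers to -1.13 and inflammatory genes to 0.24. For day 1 against day 14 signs changed for GABA receptors (0.22), astrocytes (0.60), the mitochondrial genome (0.082), Apobec3 (0.36), Cst7 (1.03), Ctsh (0.028), Ifitm3 (1.03) and Lcp2 (0.0035). The rest were 0.41 for synaptic adhesion, 0.032 for channels, 0.58 for glutamate receptors, -0.35 for microglia, 0 for inflammatory genes, 1.26 for ribosomal proteins and -0.024 for the respiratory chain. The mitochondrial genome came to 0.74 with Id2. In GFP against control, inflammatory genes (0.12) and Id2 (1.59) changed sign, with -1.28 for microglia, 0.58 for ribosomal proteins and -0.29 for the mitochondrial genome.

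With GFP cells as the control and microglia-rich cells out, day 1 values were 3.70 for Id2, -0.34 for channels, 0.45 for microglia (sign changed), 2.26 for CA markers and -0.079 for the respiratory chain, and 1.735 for the median log2 ratio, inflammatory genes, 1 day after kainate against control. Day 14 values were 0.94 for Id2, -1.22 for activity-regulated genes, -0.42 for Id and helix-loop-helix regulators, -0.77 for axon guidance, 0.054 for channels and 0.0083 for microglia. Astrocytes came to -0.50, inflammatory genes to 1.10, ribosomal proteins to -0.87 and the respiratory chain to -0.024 (sign changed).

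Without a filter on low genes, day 1 gave 0.41 for neuropeptides, -0.29 for axon guidance, -0.62 for granule markers and -1.13 for CA markers, and day 14 gave -0.78 for granule markers. Astrocytes (0.025) and interneurons (0.0062) changed sign in day 1 against day 14. The median log2 ratio, Id and basic helix-loop-helix regulators, Id2 overexpression against GFP, came to 0.0801, with -0.24 for immature neurons and 3.51 for inflammatory genes. GFP against control gave -0.25 for activity-regulated genes, 0.43 for Wnt and -3.32 for inflammatory genes. Without cells over 5% mitochondrial reads, 1 of them at day 14, the mitochondrial genome came to -0.89 at day 14, -0.21 in day 1 against day 14 and 0.39 with Id2, and astrocytes in day 1 against day 14 to 0.44 (sign changed).

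Within titles IDS up to 95, Id2 came to 8.76, axon guidance to -0.56 and Wnt to -0.54, with the median log2 ratio, mitochondrial-genome genes, Id2 overexpression against GFP, at 1.957. Within the title set of higher IDS numbers, the mitochondrial genome (-0.22), mt-Nd4 (-0.11) and mt-Nd5 (-1.45) changed sign, with 8.36 for Id2, -0.66 for activity-regulated genes, 0.82 for Wnt, 3.62 for microglia and -1.43 for CA markers.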

Other observations

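The checks of Y-linked genes and of cells numbered alike were tests chosen only after the values were seen. Single members of the fixed lists stood far from control cells after kainate. Wnt10a, a secreted Wnt ligand, stood at 45.3 CPM at day 1 and 37.2 CPM at day 14 with 0 reads in control cells (at least 1014-fold and 833-fold higher), and the Wnt receptor gene Fzd3 at 52.8 against 0.417 CPM at day 1. Ltbp1, which binds latent TGF-beta in the matrix, stood at 93.8 against 0.0744 CPM at day 1, and the activin receptor gene Acvr1c at 61.0 against 0.551 CPM, although GFP cells held 35.9 CPM of Acvr1c. Bmp3 stood at 33.3 CPM at day 14 against 0 reads (at least 745-fold higher) and also had 0 reads at day 1. Gad2, an enzyme of GABA synthesis, stood at 29.6 CPM at day 1 and 111.3 CPM at day 14 against 0.104 CPM, while Gad1, which granule cells also express, stood at 659, 1072 and 671 CPM. Vim, an intermediate filament gene of glia, stood at 134 and 53.6 CPM against 0.625 CPM, whereas Slc1a3, the glutamate transporter of astrocytes, stood at 2.20 and 1.72 CPM against 103.3 CPM.

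Hsph1, a heat shock protein gene, stood at 1440 against 498 CPM at day 1, the ribosomal protein gene Rps7 at 192 against 55.4 CPM and the complex I assembly gene Ndufaf1 at 68.9 against 15.6 CPM. With Id2 overexpression, Ddit3, a transcription factor of the unfolded protein response, stood at 152 against 52.8 CPM and the cochaperone gene Dnajb1 at 230 against 673 CPM. The adhesion gene Tenm2 stood at 120.7 against 43.9 CPM and Slitrk1 at 12.99 against 41.2 CPM.

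The 3 libraries labelled low_DG entered no comparison. Each correlated with the control cell of the same number at 0.997 to 0.999 (log2 of CPM plus 1), while the other 40 control cells reached at most 0.572 and the median over all pairs of libraries was 0.328. They are thus not counted as independent cells, and what the label means is not given in the sources used here.

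At least 10 CPM over 4 Y-linked genes was found in 58.1% of control cells (39.1% to 75.5%), 37.9% at day 1 (25.5% to 51.6%), 55.2% at day 14 (35.7% to 73.6%), 20.3% with GFP (10.98% to 32.8%) and 23.9% with Id2 (14.6% to 35.5%). The sex of the animals is not in the labels used here.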
